A study of Mus musculus with 2 samples.

How the data were processed

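RNA from sorted bone marrow HSCs of Angptl2fl/fl and Cdh5-Cre;Angptl2fl/fl mice was extracted with TRIzol and a spin column kit and sequenced as 150 bp paired-end reads on an Illumina instrument, per the labels' protocols. The surface markers of the sort, the number of mice behind each library and the library kit are not given in the sources used here. Samples were grouped by the genotype in the labels, which gives 1 library per genotype. The control sample's genotype and title are Angptl2fl/fl, while its description and its column name mention Cdh5 and Cre and no floxed allele. The column was matched to the sample by that description, and its mice are called Angptl2fl/fl here.

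The deposited table holds FPKM (fragments per kilobase of gene model and per 1000000 fragments), calculated by the authors for 54531 Ensembl genes in each library. Bowtie 0.12.2 and the genome build mm8 are named in the submitters' processing notes, with no role stated, and the counting program and annotation are not given in the sources used here. The table has no coordinates. Gene types, exon lengths and positions were taken from GENCODE mouse release M21 on GRCm38, and gene symbols from a separate list of gene names. An exon length was found for 54494 of the 54531 gene identifiers. Both a symbol and an exon length were found for 54408, and the other 123 lacked at least 1 of them. Positions are therefore GRCm38 positions and not those of the build named in the notes. The file was split on white space, because 1 row lacked a tab and 944 rows held a value padded with spaces. FPKM depends on the total of each library and on the gene model, so genes that take a large share in either library move the values of the rest, and paralogs can exchange fragments.

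FPKM multiplied by the exon length fell mostly on whole multiples of a single step per library. Within 0.02 of a whole number lay 96.5% of the 21882 genes above 0 in the control library and 96.1% of 18210 in the deletion library. The step gave the depth to which FPKM had been scaled, 17378600 and 16843100 fragments, and a fragment number per gene. Genes off the whole numbers have no fragment number or interval here. Counting intervals of a ratio are exact Clopper-Pearson intervals at 95% from the fragments of both libraries, on the ratio without a pseudocount. They cover counting error only, since duplicate reads are not separate molecules, and the interval was also computed with the fragments divided by 6, a number chosen after seeing the data.

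With 1 library per genotype no test across samples was possible. Ratios are log2((FPKM + 1)/(FPKM + 1)), deletion over control, which understates the difference of low genes, and plain folds are ratios of FPKM. Genes were counted as higher or lower at 2-fold or more on that scale among genes with a mean of at least 1 FPKM. For each of 34 gene lists, the median log2 ratio of members at a mean of at least 1 FPKM was placed among 10000 random lists of the same size matched on mean expression in 20 bins. This describes the libraries and is not a p-value, since genes are not replicates. Of the 32 lists with at least 5 such members, 4 lay above the central 95% of random lists, 7 below and 21 within. Lists of independently drawn genes would put 1.6 outside. Members of a list can vary together and some genes are in several lists. The 1.6 is therefore not the number expected between replicate libraries. The fold rule, the lists and most alternatives were fixed before the data were examined.

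The genes named were the 12 highest and 12 lowest ratios at a mean of at least 5 FPKM with a unique symbol, leaving out predicted genes, clones, pseudogenes and small RNAs, the 2 highest and 2 lowest members of each list, and Angptl2, Cdh5, Pirb, Ppard, G0s2, Ncl, Cdkn1c, Mki67, Mecom, Procr and Kit whatever their values. Not every gene that the rule selects is reported here. Other genes named, among them Prg2, Pdzk1ip1, Itga2b, S100a8, S100a9, the further members past 2-fold in the myeloid list, and the genes drawn with intervals, were chosen after their values were seen. So were 5 further lists, for primary granule, secondary and tertiary granule, monocyte and macrophage, eosinophil and plasma cell genes.

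The alternatives fixed in advance were pseudocounts of 0.1 and 5, no minimum or a minimum mean of 5 FPKM, both libraries rescaled to a common total of 1000000 (the TPM scale), ratios centred on their median, a trimmed-mean scaling, thresholds of 1.5-fold and 4-fold, random lists without matching, and the mean of a list. Added after seeing the data were a minimum mean of 200 fragments, protein-coding genes only, and scaling without mitochondrially encoded genes. The computation was tested on simulated data with counting error only. Depth and fragment numbers were recovered for 100% of 54494 genes, genes changed 4-fold in either direction were called in 100% of 50 each, and genes changed 2-fold in 14% (lower) and 18% (higher) of 50 each. Of 12144 unchanged genes, 0.618% were called. Fragments were drawn independently there, so this is not the rate of false calls in these libraries. Of 100 unchanged lists 2 fell outside the central 95%, and 100% of lists shifted by 0.5 were found. The unchanged lists were themselves random draws, so few outside was set by construction. The shifted lists were set against counting error only, so 100% is not the rate at which such lists would be found in these libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.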

Results

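Haematopoietic stem cells (HSCs) were sorted from mouse bone marrow and their RNA was sequenced. By the genotype labels, the control mice carried floxed alleles of Angptl2 (Angptl2fl/fl), a gene that encodes a secreted angiopoietin-like protein. The other mice carried the same floxed alleles with a Cre recombinase driven by the promoter of Cdh5, the endothelial cadherin gene (Cdh5-Cre;Angptl2fl/fl), and the labels describe them as lacking Angptl2 in endothelial cells. The comparison asks how the transcriptome of HSCs differs between these genotypes. The labels do not say whether HSCs kept Angptl2, so its loss in the endothelium cannot be told apart from a loss in HSCs. There was 1 library per genotype, called here the control library and the deletion library. The control library's title and genotype are Angptl2fl/fl, but its description and its column name mention Cdh5 and Cre. They mention no floxed allele, unlike those of the deletion library. Whether the control mice carried Cre, and whether they carried floxed alleles, is therefore not settled by the labels. With 1 library per genotype the differences have no replicate check, no p-value is given, and "higher" and "lower" describe these 2 libraries. The deposited values are FPKM for 54531 genes. Of the genes above 0 with an exon length, 96.5% in the control library and 96.1% in the deletion library lay within 0.02 of a whole number of fragments, which put the depth at 17378600 fragments for the control library and 16843100 for the deletion library. In the control library 21891 genes were above 0, against 18217 in the deletion library. At 1 FPKM or more the numbers were 12505 and 12103.

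Angptl2 itself (chromosome 2, 33216069 to 33247717, plus strand, GRCm38) was barely detected in the HSC libraries. Its level was 0.27 FPKM in the control library and 0.18 FPKM in the deletion library, from 29 and 19 fragments. The 95% counting interval of the log2 ratio ran from -1.48 to 0.32, so a difference was not detectable at this depth. The labels place the deletion in endothelial cells and do not say whether HSCs kept the gene. At so low a level these values do not check the genotype labels. Cdh5, the gene whose promoter drives Cre, was at 0.027 FPKM in the control library and was listed at 0 in the deletion library.

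The deletion library held more mRNA of neutrophil serine proteases and their companions, such as Mpo at 723 against 281 FPKM and Elane at 1084 against 423 FPKM. It held less mRNA of later neutrophil granule proteins, such as Ltf at 36.3 against 112 FPKM. Pf4, a platelet chemokine, was 3.16-fold higher, at 94.7 against 29.9 FPKM. Prg2, the major basic protein of eosinophil granules, was 23.5-fold lower, at 2.13 against 49.9 FPKM. Of 12325 genes with a mean of at least 1 FPKM, 305 were at least 2-fold higher in the deletion library and 417 at least 2-fold lower, on the log2(FPKM + 1) scale. Gene lists are counted on that scale too, on which low genes can stay under 2-fold with a plain ratio of FPKM past it. The other 11603 genes (94.1%) lay between. The log2 ratios had a median of -0.011 and quartiles of -0.20 and 0.18. Of 10237 protein-coding genes, 50 were higher and 77 lower by that rule, and of 97 immunoglobulin segments 18 were higher and 67 lower. The other gene types, among them pseudogenes and noncoding RNAs, held most of the calls, with 237 higher and 273 lower of 1991 genes. Raising the minimum mean to 5 FPKM left 83 higher and 97 lower genes of 7658, and counting at a mean of at least 200 fragments, a limit chosen after seeing the data, left 37 and 41.

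**Figure D1:**
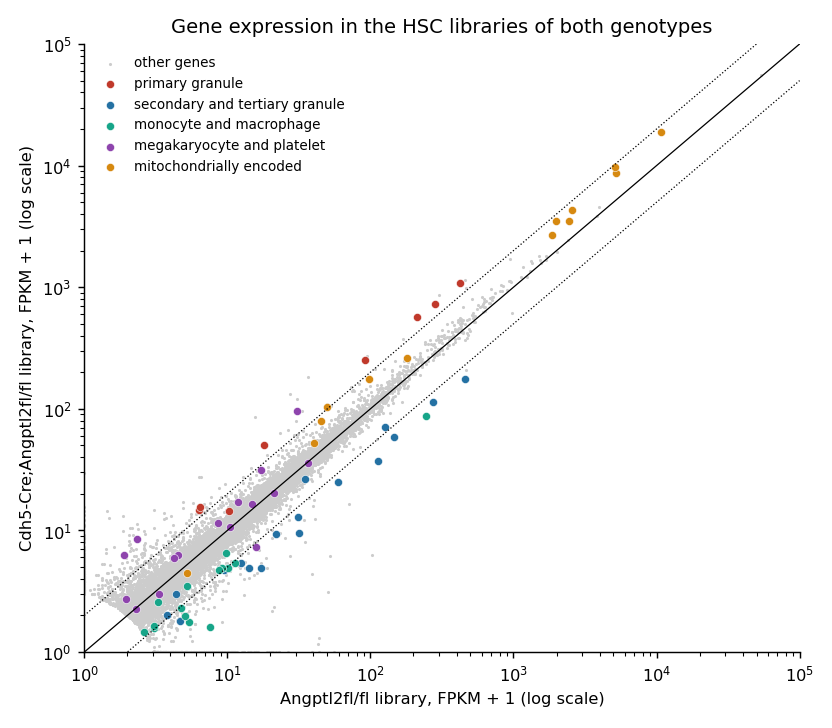
Each point is a gene with a mean of at least 1 FPKM, placed by its FPKM + 1 in the Angptl2fl/fl library (horizontal, log scale) and in the Cdh5-Cre;Angptl2fl/fl library (vertical, log scale), with solid and dotted lines at equality and at 2-fold. Colours mark gene lists, of which the primary granule, secondary and tertiary granule, and monocyte and macrophage lists were drawn up after the data were seen. Of the primary granule list 7 of 8 genes, such as Mpo (281 and 723 FPKM), lie above the upper dotted line. Of the secondary and tertiary granule list 14 of 18 genes, such as Ltf (112 and 36.3 FPKM), lie below the lower one.

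Of the 28 genes of the myeloid and neutrophil list, 6 were at least 2-fold higher in the deletion library, 12 at least 2-fold lower and 10 between. The 6 higher genes were Ms4a3, Ctsg, Prtn3, Mpo, Elane and Fcgr3. Ctsg (cathepsin G), Prtn3 (proteinase 3), Elane (neutrophil elastase) and Mpo (myeloperoxidase) encode proteins of the primary granules, which form at the promyelocyte stage. Ms4a3, expressed in granulocyte and monocyte progenitors, was at 49.9 against 16.9 FPKM, and Ctsg was at 252 against 90.1 FPKM. The 12 lower genes were Csf1r, Ltf, Lyz2, Ngp, Retnlg, Mmp9, Camp, Lcn2, Mmp8, Ctss, F13a1 and Ly6g. Ltf (lactoferrin), Camp (cathelicidin), Lcn2 (lipocalin 2) and Mmp8 (collagenase) are proteins of secondary granules, which form later in neutrophil maturation, and Csf1r is the receptor that monocytes and macrophages need. Csf1r was at 0.75 against 4.44 FPKM, and Lyz2 (lysozyme) at 86.1 against 242 FPKM. Without the pseudocount, the log2 ratio of Mpo was 1.36 (counting interval 1.34 to 1.39) and that of Ltf -1.63 (-1.70 to -1.56). S100a8 and S100a9, abundant in mature neutrophils, stood at 407 against 484 FPKM and 615 against 970 FPKM. The median log2 ratio of the list was -0.63, at percentile 0 among 10000 random lists matched on mean expression, which is a description of these libraries and not a p-value.

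In the antigen presentation, dendritic and macrophage list, 13 of 15 measured genes had a log2 ratio below 0, with 2 at least 2-fold lower. Those were C1qa, a complement gene of macrophages, at 3.88 against 9.07 FPKM, and Cd74, the MHC class II invariant chain, at 17.6 against 36.4 FPKM. Vcam1 stood out at 5.78 against 3.69 FPKM. The list median was -0.39 (percentile 0 among random lists), and with only genes of at least 200 fragments it was -0.17 (percentile 8.11), inside the central 95%. Mast cell and basophil genes had a median of -0.19 (percentile 5.61), with Prss34 lowest at 3.95 against 12.3 FPKM.

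**Figure D2:**
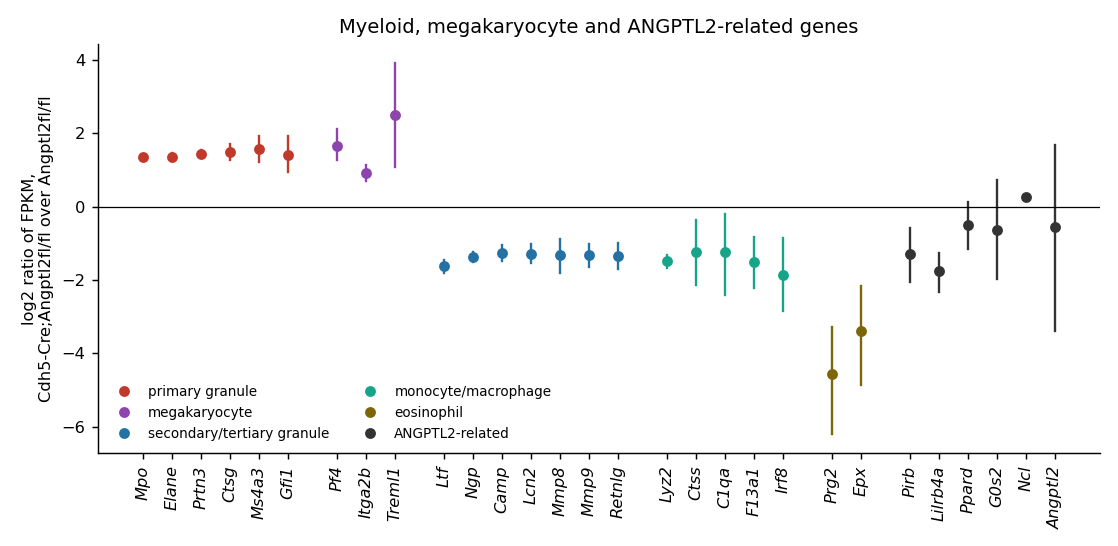
Points give the log2 ratio of FPKM, Cdh5-Cre;Angptl2fl/fl over Angptl2fl/fl and without a pseudocount, for genes grouped by colour, which were chosen for display after the data were seen. Lines are 95% counting intervals computed with the fragment numbers divided by 6, the most common number per gene in the deletion library, and cover counting error only. Mpo lies at 1.36, Ltf at -1.63 and Prg2 at -4.55, while the interval of Ppard runs from -1.17 to 0.12.

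In the megakaryocyte and platelet list, 3 of 16 genes were at least 2-fold higher in the deletion library, 1 was lower and 12 lay between, with 11 above 0 and 5 below. The median log2 ratio was 0.45 (percentile 100), and among genes with a mean of at least 5 FPKM it was 0.16 (percentile 95.2), inside the central 95% of random lists. The 3 were Treml1 at 7.58 against 1.35 FPKM, Ppbp at 5.32 against 0.90 FPKM and Pf4, all of them products of platelet granules. Itga2b, the platelet integrin subunit that also marks early progenitors, was at 30.7 against 16.3 FPKM. Thbs1 (thrombospondin 1) went the other way, at 6.26 against 14.8 FPKM.

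Genes used as HSC markers were mostly slightly lower. Of 25 measured genes, 21 had a log2 ratio below 0, none of the 25 passed 2-fold on the log2(FPKM + 1) scale, and the median was -0.18 (percentile 0.68). Vldlr was lowest at 0.40 against 1.66 FPKM, a log2 ratio of -0.93 that became -1.83, past 2-fold, with a pseudocount of 0.1, followed by Pdzk1ip1 at 6.95 against 11.6 FPKM. Vwf, at 4.90 against 3.21 FPKM, and Ctnnal1, at 1.57 against 1.22 FPKM, were highest. Mecom, a transcription factor needed for HSC maintenance, was at 1.36 against 1.67 FPKM, Procr (the protein C receptor) at 4.68 against 5.33 FPKM, and Kit, the stem cell factor receptor, at 48.8 against 54.3 FPKM. The counting interval of the Procr ratio, -0.50 to 0.12, included equality. With the mean of the list in place of its median the percentile was 8.80, inside the central 95%.

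Quiescence and cell cycle genes differed little. Of 22 quiescence genes, 18 were below 0 and the list median was -0.080 (percentile 8.31). The exception past 2-fold was Gfi1, a transcriptional repressor that also acts in neutrophil progenitors, at 14.5 against 5.45 FPKM. Cdkn1c, which encodes the cell cycle inhibitor p57, was at 1.28 against 1.47 FPKM with a counting interval of -0.81 to 0.41. S phase genes had a median of 0.0093 (percentile 35.1; -0.14 with both libraries rescaled to a common total), from E2f1 at 21.8 against 27.2 FPKM to Tipin at 61.9 against 48.5 FPKM. Mitosis genes had a median of 0.13 (percentile 98.1) that turned to -0.016 with both libraries rescaled to a common total, with Cdc25c at 14.4 against 9.61 FPKM and Mki67, a marker of cycling cells, at 75.1 against 86.3 FPKM. That rescaling moved the median of all genes from -0.011 to -0.15, and relative to other genes the mitosis list then stood at percentile 97.6. With a pseudocount of 5 it stood at 96.9 and with the mean of the list at 92.4, inside the central 95%. Replication-dependent histone genes had a median of 0.094 (percentile 89.8; -0.018 rescaled; 0.43 and percentile 100 at a mean of at least 5 FPKM), with Hist1h4a at 0.33 against 3.31 FPKM.

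ANGPTL2 is proposed to act on HSCs through its receptor PIRB, the transcription factor PPARD and G0s2, so these genes were read out whatever their values. Pirb (chromosome 7, 3711409 to 3720391, minus strand, GRCm38) was 2.43-fold lower in the deletion library, at 1.95 against 4.74 FPKM from 147 and 368 fragments. The log2 ratio was -0.96 with the pseudocount of 1, short of the 2-fold threshold, and -1.24, past it, with a pseudocount of 0.1. The counting interval without a pseudocount was -1.56 to -1.0. Ppard (chromosome 17, 28232700 to 28301474, plus strand) was at 1.71 against 2.44 FPKM, a log2 ratio of -0.34. G0s2 (chromosome 1, 193272161 to 193273217, minus strand), an inhibitor of triglyceride lipase, was at 3.54 against 5.48 FPKM, a log2 ratio of -0.51. Counting intervals of -0.77 to -0.26 for Ppard and -1.16 to -0.11 for G0s2 excluded equality with fragments taken as independent, but with the fragments divided by 6 both included it, at -1.17 to 0.12 and -1.98 to 0.72. Ncl (nucleolin) was at 182 against 151 FPKM, a log2 ratio of 0.26. Of the 15 measured genes of the list of ANGPTL receptors and their proposed pathway, 1 passed 2-fold on the log2(FPKM + 1) scale, Lilrb4a, an inhibitory receptor of the same family as Pirb, at 2.68 against 9.13 FPKM. Both Pirb and Lilrb4a have close paralogs, so fragments may have been split between gene copies. Lilr4b, a paralog of Lilrb4a read out after the data were seen, was lower as well, at 8.62 against 22.2 FPKM. The list median was -0.12 (percentile 3.50), inside the central 95%, and with a pseudocount of 5 the percentile was 1.03, outside it. Fatty acid oxidation genes, many of them PPAR targets, had a median of 0.057 (percentile 82.2), which was -0.085 with both libraries rescaled to a common total and -0.0077 with mitochondrially encoded genes left out of the scaling. None of the 27 passed 2-fold, and the ends were Cpt1a at 35.9 against 47.2 FPKM and Etfb at 11.8 against 7.86 FPKM.

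**Figure D3:**
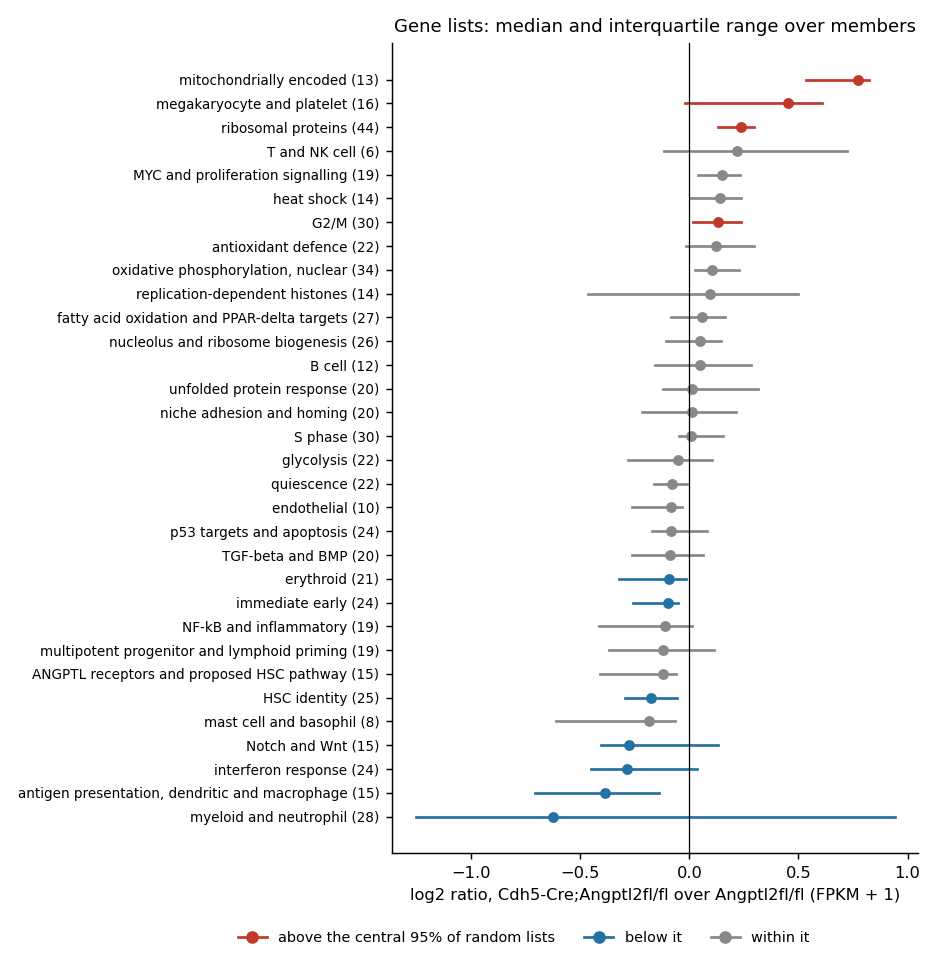
Points are the median and lines the interquartile range, over members, of the log2 ratio of FPKM + 1 (Cdh5-Cre;Angptl2fl/fl over Angptl2fl/fl) for each of the 32 gene lists with at least 5 measured genes (number in brackets). Red and blue lists lie above and below the central 95% of 10000 matched random lists, from 0.77 for mitochondrially encoded genes to -0.63 for the myeloid and neutrophil list. The red G2/M list, at 0.13, turns to -0.016 when both libraries are rescaled to a common total, and the grey S phase, fatty acid oxidation, nuclear oxidative phosphorylation, niche adhesion, nucleolus, heat shock, unfolded protein response, antioxidant, B cell and histone lists also turn below 0 there.

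Of 13 mitochondrially encoded mRNAs, 12 had a log2 ratio above 0, 1 was at least 2-fold higher in the deletion library, and the median was 0.77 (percentile 100). The gene past 2-fold was mt-Atp6 at 103 against 48.9 FPKM, mt-Cytb (cytochrome b) was at 9721 against 5131 FPKM, and mt-Atp8 went the other way at 3.49 against 4.23 FPKM. The mitochondrial ribosomal RNA mt-Rnr1 was 2.85-fold higher, at 859 against 301 FPKM. Mitochondrially encoded genes made up 13.7% of the FPKM total in the deletion library and 8.91% in the control library. Nuclear genes of oxidative phosphorylation had a median of 0.11 (percentile 79.7; -0.041 rescaled to a common total), with Cycs (cytochrome c) highest at 38.9 against 22.9 FPKM and Ndufa2 lowest at 89.9 against 104 FPKM. Ribosomal protein genes had a median of 0.24 (percentile 99.95), with 41 of 44 above 0 and none of the 44 past 2-fold on the log2(FPKM + 1) scale, and the ends were Rpl24 at 5.19 against 2.51 FPKM (past 2-fold with a pseudocount of 0.1, at 1.02) and Rpl38 at 452 against 488 FPKM. With the mean of the list the percentile was 96.5, inside the central 95%. Nucleolar and ribosome assembly genes had a median of 0.048 (percentile 49.1; -0.099 rescaled), with Npm1 highest at 537 against 408 FPKM. The median of MYC genes and their growth targets was 0.15 (percentile 92.8). Against random lists not matched on expression the nuclear oxidative phosphorylation and MYC lists stood outside, at percentiles 97.5 and 97.9. Glycolysis genes had a median of -0.051 (percentile 10.6), with Pgam1 at 51.9 against 36.2 FPKM and Slc2a3, a glucose transporter, at 14.8 against 20.6 FPKM.

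Of 24 interferon-stimulated genes, 17 were below 0 and the median was -0.29 (percentile 0.03), with Oas1a at 4.44 against 8.88 FPKM and Irf7 at 3.38 against 6.80 FPKM. At a mean of at least 5 FPKM the median was -0.10 (percentile 13.9), and with the mean of the list the percentile was 5.96. In the NF-kB list, 2 of 19 genes passed 2-fold, Tlr2 at 0.97 against 4.07 FPKM and Tnf at 0.65 against 2.84 FPKM, with a list median of -0.11 (percentile 6.26). Immediate early genes, which are induced when tissue is dissociated, had a median of -0.098 (percentile 0.14; 9.46 against random lists not matched on expression), with Fosl2 lowest at 9.34 against 17.9 FPKM. Of 15 Notch and Wnt genes 10 were below 0, with a median of -0.28 (percentile 0.32; 7.69 without a minimum FPKM and 18.7 for the mean of the list), from Notch1 at 1.74 against 3.93 FPKM to Dtx4 at 3.58 against 1.54 FPKM. The remaining signalling and stress lists lay inside the central 95%. Medians were -0.090 for TGF-beta and BMP (percentile 17.3), -0.084 for p53 targets and apoptosis (10.6), 0.14 for heat shock (91.3), 0.013 for the unfolded protein response (38.1) and 0.12 for antioxidant defence (91.0). The last 3 turned below 0 with both libraries rescaled to a common total. In the antioxidant list Hmox1, a haem-degrading enzyme abundant in macrophages, was 2.39-fold lower at 4.34 against 10.4 FPKM. Niche adhesion and homing genes had a median of 0.013 (percentile 50.6; -0.13 rescaled) and a mean of -0.042, with the leukocyte integrin genes Itgal at 2.47 against 5.72 FPKM and Itgb2 at 14.9 against 26.3 FPKM lowest.

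Erythroid genes were abundant in both libraries. Car1 (carbonic anhydrase 1) was at 1629 FPKM in the deletion library and 1315 in the control library. The lowest ratios of the erythroid list were those of Alas2, the first enzyme of erythroid haem synthesis, at 1.51 against 4.53 FPKM and Hbb-bt, an adult beta globin, at 12.2 against 25.2 FPKM. The median of 21 erythroid genes was -0.094 (percentile 0.28; 13.2 against random lists not matched on expression). Progenitor and lymphoid priming genes had a median of -0.12 (percentile 4.38), with Ctsg and Plac8 (108 against 49.0 FPKM) highest and Wfdc17 (0.56 against 2.27 FPKM) and Irf8 (0.58 against 2.10 FPKM) lowest. Endothelial genes had a median of -0.084 (percentile 28.0), from Robo4 at 2.55 against 3.43 FPKM to Vwf. Only 4 stromal genes reached 1 FPKM, among them Fn1 (fibronectin), which macrophages also express, at 0.61 against 6.57 FPKM. Of the sex-linked genes, Xist (26.6 and 34.4 FPKM) and the Y-linked Ddx3y (9.48 and 7.80 FPKM) and Eif2s3y (10.3 and 8.44 FPKM) were present in the deletion and control libraries alike.

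Immunoglobulin genes took the 5 highest and the 9 lowest places in the ranking of ratios from which genes were named. Igkv8-21, Ighv1-80 and Igkv12-44 were at 54.5, 42.5 and 38.2 FPKM in the control library and were listed at 0 in the deletion library. Ighg2c, an IgG heavy chain constant gene, was at 0.31 against 43.0 FPKM, and Ighv1-81 at 5.24 against 102 FPKM. In the other direction Igkv1-88 and Igkv6-13 were listed at 0 in the control library and stood at 28.5 and 13.6 FPKM in the deletion library. Ighv1-9 was at 131 against 26.4 FPKM, Iglv2 at 121 against 29.7 FPKM and Iglc2 at 62.7 against 22.5 FPKM. Of 80 V segments with a mean of at least 1 FPKM, 15 were at least 2-fold higher and 58 lower, and their segments resemble each other enough that fragments may have been assigned to the wrong copy. All V segments together held 714 FPKM in the deletion library and 1276 FPKM in the control library. Igkc, the kappa constant gene, was at 208 against 467 FPKM, while Cd79a, a subunit of the B cell receptor complex, was at 6.93 against 3.48 FPKM. The B cell list of 12 genes had a median of 0.047 (percentile 65.1), a mean of -0.12 and a median of -0.075 with both libraries rescaled to a common total. T and NK cell genes, 6 of which were measured, had a median of 0.22 (percentile 93.5), led by Nkg7 at 78.0 against 29.1 FPKM.

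**Figure D4:**
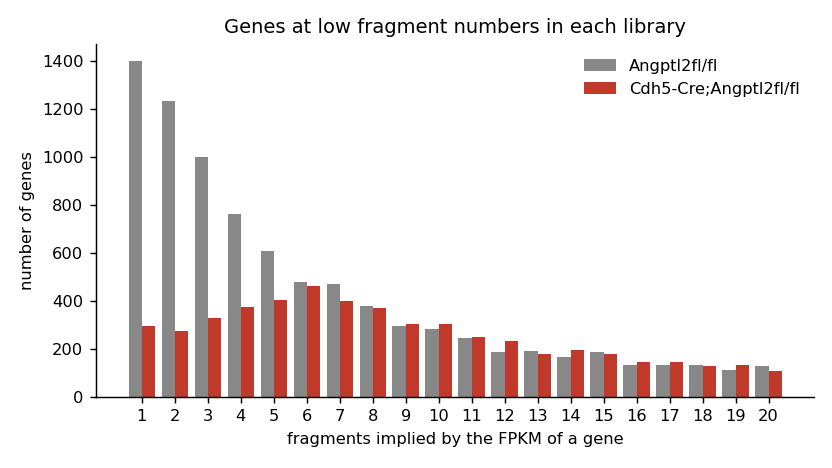
Bars give the number of genes (vertical) at each fragment number from 1 to 20 implied by the FPKM (horizontal) in the Angptl2fl/fl library (grey) and the Cdh5-Cre;Angptl2fl/fl library (red). At 1 fragment there are 1399 genes in the control library and 295 in the deletion library, and at 6 fragments 476 and 461.

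Low-level genes were fewer in the deletion library, which limits comparisons near the floor. At 1 fragment there were 1399 genes in the control library and 295 in the deletion library. Of 565 protein-coding genes with 8 to 12 fragments in the control library, 36.3% were at 0 in the deletion library (exact 95% interval 32.3 to 40.4%). Of 600 with 8 to 12 fragments in the deletion library, 18.0% were at 0 in the control library (15.0 to 21.3%). For a gene of 1 kb, 3 fragments, the limit that a count of 0 allows, correspond to 0.173 FPKM in the control library and 0.178 FPKM in the deletion library. Fragments are not independent molecules, so all intervals and limits cover counting error only.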

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

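The limits on fragments, on gene type and the scaling without mitochondrially encoded genes were chosen after seeing the data. Against 305 higher and 417 lower genes, a pseudocount of 0.1 gave 471 higher and 599 lower, a pseudocount of 5 gave 74 and 118, no minimum FPKM 428 and 683, and a minimum mean of 5 FPKM 83 and 97. A threshold of 1.5-fold gave 708 and 749, 4-fold 75 and 165, at least 200 fragments 37 and 41, and protein-coding genes only 50 and 77, since these settings test fewer genes or move the threshold itself, as the pseudocount and the minimum set how many low genes count. Rescaling to a common total gave 338 and 590, centring 315 and 411, trimmed-mean scaling 314 and 413, and scaling without mitochondrially encoded genes 270 and 432. With the mean of each list, 2 lists lay above and 4 below the central 95% of random lists, against 4 and 7 with the median, and the cause was not tested. Under the other settings run, 3 to 6 lists lay above and 5 to 8 below. The G2/M median, 0.13, became -0.016 when both libraries were rescaled to a common total, which takes more from the deletion library, its FPKM total being 419943 against 379052. Across lists and settings 416 values kept their place against the central 95%, 12 moved inside it and 4 outside. The 1 other, the G2/M list rescaled to a common total, stayed above it at percentile 97.6 with a median below 0. For 626 named or listed genes with a counting interval, 3756 log2 ratios were recomputed over the settings, of which 3114 moved by less than their counting error, 642 by more and 188 changed sign. None of the 456 for the 76 genes past 2-fold changed sign, which was certain in advance. A pseudocount keeps the sign, and the rescalings move ratios by far less than 2-fold. The mitochondrially encoded and the myeloid and neutrophil lists stayed outside in all 12 alternatives run for them, and in the 11 that use a median these were 0.63 to 0.79 and -0.79 to -0.37. The Angptl2 log2 ratio lay between -0.39 and -0.024 in the 6 alternatives that gave it, and the settings of the minimum FPKM do not bear on it. No paired analysis was possible because there is 1 library per genotype, and for the same reason no replicate could be left out. Depth limits genes near 0.173 FPKM at 1 kb, and the deletion library has few genes at the lowest fragment numbers.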

Other observations

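The outcome of the duplicate-fragment test was written down, as a most common fragment number, before the result it measures was seen. The ratio of genes at 6 over genes at 1 was not part of that outcome. The other tests in this part were chosen after the results had been seen. The division by 6 and the 5 added gene lists were too. Split by stage, the myeloid genes past 2-fold went in opposite directions. Of the 8 genes of the primary granule list, 7 were at least 2-fold higher in the deletion library, with a median log2 ratio of 1.36. The list also holds Cebpa, Gfi1 and Ms4a3, which do not encode granule proteins. Prss57, a granule serine protease, was at 13.7 against 5.38 FPKM. The secondary and tertiary granule list also holds genes of surface proteins and receptors, and 14 of its 18 genes were at least 2-fold lower, with a median of -1.25. Among them were Cd177, a neutrophil surface protein, at 8.47 against 30.9 FPKM and Il1r2, a decoy receptor for interleukin 1, at 3.89 against 16.3 FPKM. Of 15 monocyte and macrophage genes, 7 were at least 2-fold lower, with a median of -0.97. Of 5 eosinophil genes 2 were, Prg2 and Epx (eosinophil peroxidase, 0.78 against 8.14 FPKM), with a median of -0.83, while Siglecf was higher at 3.81 against 2.87 FPKM. The 7 plasma cell genes other than immunoglobulins had a median of -0.23, with 5 below 0 and 2 above. Of these 1 was at least 2-fold lower, Mzb1 at 2.10 against 5.21 FPKM. Of the 53 genes measured in these lists, 30 are also in the lists fixed in advance, and the 5 lists were drawn up after the values were seen, so their medians describe and do not test.

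Several levels describe what the libraries contain, named after their values were seen. The erythroid genes Car1 (1315 and 1629 FPKM in the control and deletion libraries), Car2 (703 and 832), Aqp1 (540 and 514) and Klf1 (176 and 191) exceeded the HSC marker genes Procr (5.33 and 4.68) and Slamf1 (0.40 and 0.55). Sumo2 was at 40.3 FPKM in the control library and 11.5 FPKM in the deletion library. Gm23935, a predicted small RNA gene, held 53963 and 55555 FPKM. V segments of immunoglobulins above 0 numbered 96 in the control library and 47 in the deletion library, with 30 shared. Mitochondrially encoded genes held 3.94% and 6.56% of fragments.

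The deletion library has few genes at 1 to 3 fragments. A cut-off on fragment numbers is argued against by the 568 genes at 1 or 2 fragments, and shallower sequencing by the ratio of depths of 0.969. A cut-off on FPKM would act by gene length as well, which that count ignores, and was not tested. Among genes at 0 in the control library the most common number in the deletion library was 6. The outcome written beforehand for duplicate fragments from few starting molecules, 4 or more and not 1, was met. Among genes at 0 in the deletion library, the control library had 1038 at 1 fragment and 265 at 6. In the deletion library genes at 6 over genes at 1 came to 1.13 (exact 95% interval 0.864 to 1.49). Counting error therefore leaves open whether 6 or 1 was the more common number there. Equality is not the pattern of the control library, where genes at 1 far outnumbered genes at 6. The ratio was not part of the written outcome and decides neither for nor against duplicate fragments, which are not settled as the cause. Fewer genes expressed in the HSCs of the deletion mice also stay open, which was not tested.

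Primary granule genes were higher and secondary granule genes lower in the deletion library. A single scaling difference, which moves all genes alike, is argued against by the interquartile range of 2.19 of the myeloid and neutrophil list fixed in advance (0.38 for all genes), and counting error by 25 of its 27 genes with fragment numbers, 9 above and 16 below equality, whose intervals excluded it with fragments divided by 6, although for Ly6g and Itgam a division by 7 would have included it. A lower share of mature neutrophils would raise genes of other cell types alike. The erythroid list, fixed in advance, was not raised as a whole, with a median of -0.094 and an upper quartile of -0.015. The primary granule genes had a lower quartile of 1.25 and a median of 1.36. Their list was drawn up after the values were seen, so the gap between the lists describes and does not test. For the lower secondary granule genes a lower share of mature neutrophils stays open despite the sort for HSCs. S100a8 and S100a9 had a mean log2 ratio of -0.45, between equality and the secondary granule list median of -1.25. The genotype stays open and untested, because with 1 library per genotype it cannot be told apart from the animals or the sort.

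Pirb, Ppard and G0s2 were lower in the deletion library. With fragments divided by 6, counting error alone is argued against for Pirb, whose upper bound was -0.60 and would include 0 only at a division by 19. For Ppard and G0s2 the upper bounds of 0.12 and 0.72 include equality, so counting error from few molecules may account for their lower values. Fewer mature myeloid cells, which also express Pirb, cannot be told apart from a change within HSCs, since each library pools the RNA of all sorted cells. The log2 ratio of Pirb, -0.96, lay inside the interquartile range of -1.37 to -0.91 of 33 mature myeloid genes. Those are the added secondary and tertiary granule and monocyte and macrophage lists, all of whose measured genes were below 0. They were drawn up after the values were seen, so that place describes and does not test. An effect of the genotype on any of the 3 genes stays open and was not tested.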
